A study of Mus musculus with 6 samples.

How the data were processed

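Small RNA was sequenced from the pancreas of C57BL/6 mice in 6 libraries. The 3 control libraries came from saline-treated mice and carry the replicate numbers 43, 44 and 45. The 3 model libraries, numbered 56, 57 and 59, came from mice given caerulein, a cholecystokinin analogue that overstimulates acinar cells, together with lipopolysaccharide (LPS), a bacterial cell wall component. Per the labels' protocols, RNA of 18 to 30 nt was cut from a gel, adapters carrying unique molecular identifiers were ligated, and the product was amplified by PCR. Groups were read from the sample titles. The labels do not state that each library came from its own mouse, so p-values measure the spread between these libraries, which may be partly technical.

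The authors deposited one table with a row per mature miRNA arm. Its count columns hold whole-number read counts, per the file headers, with no normalization. A second set of columns holds the authors' RPM values, in which each count is divided by a library total of 22055639 to 27876715 that was recovered here from the ratio of count to value over rows of at least 100 counts. What that total counts is not given in the sources used here. The submitters' processing notes name Bowtie2 and the assembly GRCm38.p6 without a role or a version. Whether the counts were collapsed on molecular identifiers is not given in the sources used here, so intervals and floors cover counting error only. PCR duplicates, if kept, would make counts look more precise than the molecules behind them. Ligation bias would distort levels between miRNAs, and that it acts alike in all libraries is assumed here, not tested.

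The table held 1414 rows, of which 1104 were known mouse miRNA arms and 310 carried identifiers that mark them as predicted. The mature sequence of 14 rows repeated that of an earlier row, and in all 14 the counts were identical as well, so such rows are not separate measurements. Total counts per library ran from 1943693 to 3006220. A count of 0 in one library allowed up to 3 counts, or 0.998 to 1.54 CPM (counts scaled to a common library total). Every per-sample column of the table was assigned to a library by its name. Replicates were compared before they were averaged: the chi-square per degree of freedom ran from 124 to 293 over the 6 pairs within groups, where sampling noise alone gives about 1, so no library was a copy of another. Pearson's r across miRNAs, on log2(CPM + 1), was 0.963 to 0.972 within groups and 0.942 to 0.968 between them, and miRNAs are not independent replicates.

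Counts were tested with edgeR 4.0.16 in R 4.3.3. Rows were kept by filterByExpr at its defaults (minimum count 10, minimum total 15), which left 499 rows, 447 known and 52 predicted. Libraries were scaled with TMM factors, dispersions were estimated robustly, and the groups were compared with the two-sided quasi-likelihood test (glmQLFit with robust estimation and the installed version's default dispersion method, then glmQLFTest). P-values were adjusted by Benjamini and Hochberg's method over the 499 rows, with a threshold of 0.05. CPM values below are TMM-scaled. The share of counts in tested rows was at least 99.9% in each library.

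A set of 18 miRNA lists was fixed by name before the data were examined: pancreatic acinar-enriched, pancreatic islet-enriched, epithelial, leukocyte-enriched, LPS- and NF-kB-induced, erythroid, endothelial, mesenchymal and smooth muscle, striated muscle, liver and intestine, neural, the miR-29 family, the miR-34 family, hypoxia, the miR-17~92 and paralogous clusters, the let-7 family, the Dlk1-Dio3 imprinted cluster and the Sfmbt2 intron cluster. Both arms of a hairpin counted as members. Lists with at least 3 tested members were tested with camera in limma 3.58.1 at its preset correlation of 0.01, adjusted over 16 lists. Camera with an estimated correlation and fry, in a directional form and a mixed form that takes both directions together, were run beside it. Shares of counts were compared with a two-sided exact permutation test, for which 3 libraries against 3 cannot give a p below 0.1. The log2 ratio of the 5p to the 3p arm, with 1 count added to each, was tested with limma and robust empirical Bayes for the 128 hairpins with a mean of at least 10 counts on both arms.

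The miRNAs named were chosen by a rule fixed before the data were examined. It takes the 8 largest increases and the 8 largest decreases among calls whose groups did not overlap and whose higher mean was at least 10 CPM, the 6 most abundant rows, the 3 most abundant tested members of each list, and 11 markers of acinar and islet cells, inflammation and blood. The text names only part of those the rule took and gives the rest by list, a cut made after the values had been seen. Named outside the rule, also after their values were seen, were miR-146b-5p, miR-17-5p, miR-103-3p, miR-202-5p and several 3p arms of the let-7 family.

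Hairpins were placed on GRCm38 with the GENCODE mouse release M21 annotation by name, chromosome and sequence. This placed 439 of the 447 known tested rows (98.2%), and where a mature sequence comes from several hairpins the placement follows the one named in the table.

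The scripts were tested on simulated data. In 10 simulated data sets for the model against control comparison over 499 rows, with 200 rows changed, the test recovered 30.5% of rows changed 2-fold and 86.4% of rows changed 4-fold, and 2.67% of its calls were false. Without any change it called 0.1 rows per set on average and no list in any set. A list raised 2-fold was called in 10 of 10 sets. The simulated rows were drawn independently, so these sets cannot show how often correlated members give a false list call. In the real data the estimated correlation within lists ran from -0.146 for the miR-29 family to 0.601 for leukocyte-enriched miRNAs. Of 20 arm ratios shifted 4-fold, 53.5% were recovered, beside 1 false call per set. These rates hold for the simulated settings only. With 200 rows changed, against 6 called in the real data, the adjusted threshold is easier to pass. Simulated dispersions followed the fitted trend, without a spread between rows of like abundance. Recovery in the real data may therefore be lower.

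Alternatives tried were RLE, upper quartile and no scaling factors, no filter, a filter of 10 CPM in 3 libraries, known miRNAs only, a log2 fold change of at least 1 as well, DESeq2 1.42.0, limma-voom, leaving out each library in turn, the more abundant arm only, other denominators for shares, and other minimums and pseudocounts for arm ratios. Scaling by the library totals behind the authors' RPM values, keeping identical sequences once, and edgeR's newer quasi-likelihood dispersion were added after the data had been seen.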

Results

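The libraries measured mature miRNAs in pancreas from an acute pancreatitis model and its saline control, 3 libraries per group. Per the labels, mice received 7 intraperitoneal injections 1 hour apart, with caerulein at a stated 50 mg/kg and LPS added to the last one in the model group, and tissue was taken 24 hours after the start. The dose is given in the unit the labels state. Total miRNA counts were 2629801, 2381522 and 1943693 in control replicates 43, 44 and 45, and 2489009, 3006220 and 2884794 in model replicates 56, 57 and 59. The 10 most abundant rows took 37.2% ± 1.03 of counts in control and 31.9% ± 1.89 in model libraries (SD, n = 3 each; exact permutation p = 0.1, the smallest possible; adjusted p = 0.14 over 7 library measures).

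The single comparison of the design asked which miRNAs differ between pancreas of mice given caerulein with LPS and the saline control. Of the miRNAs tested, 5 were higher and 1 was lower in the model group. The star strand of miR-21, miR-21a-3p, had the lowest p of all and rose from 31.2 ± 16.2 to 736 ± 262 CPM (SD, n = 3), a log2 fold change of 4.55 (SE 0.47, edgeR adjusted p = 0.0077). The myeloid miRNA miR-223-3p rose from 321 ± 129 to 2162 ± 60.8 CPM, by 2.75 on the log2 scale (SE 0.31, edgeR adjusted p = 0.0077). The proliferation-associated miR-18a-5p, from the miR-17~92 cluster, rose from 46.8 ± 4.72 to 173 ± 19.1 CPM, by 1.88 (SE 0.23, edgeR adjusted p = 0.0077). Lower levels were involved for miR-212-5p, which rose from 7.35 ± 1.69 to 30.4 ± 1.16 CPM (log2 fold change 2.03, SE 0.30, edgeR adjusted p = 0.0207). All 3 model libraries lay above all 3 controls for each of these.

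The remaining increase was that of miR-147-3p, a miRNA induced through Toll-like receptors, with 3 counts over the control libraries together and 14.9 ± 7.31 CPM in the model libraries (SD, n = 3). The ratio of its TMM-scaled rates was 31.2, with a 95% exact Poisson interval of 10.5 to 153 that covers counting error only (edgeR adjusted p = 0.0273). The single decrease was a predicted miRNA listed on chromosome X with the sequence CGGGCGUGGGGGUGGGGGG, which fell from 193 ± 63.1 to 48.7 ± 10.6 CPM (log2 fold change -1.98, SE 0.32, edgeR adjusted p = 0.0273). That sequence matched no annotated transcript, and whether it is a miRNA was not examined. The search covered GENCODE M21 transcripts only. The most abundant predicted row, which ends in CCA as mature tRNAs do, matched none either, so sources outside that annotation stay open.

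In GRCm38, Mir21a lies on chromosome 11 from 86584067 to 86584158, on the minus strand and overlapping an exon of Vmp1. Mir223 lies on chromosome X from 96242817 to 96242926, within an exon of the noncoding F630028O10Rik. The hairpin of miR-18a-5p, Mir18, is on chromosome 14 from 115043851 to 115043946, in an exon of the noncoding host Mir17hg. Mir212 is on chromosome 11 from 75173388 to 75173478, in an intron of 1700016P03Rik, and Mir147 is on chromosome 2 from 122640803 to 122640881, overlapping an exon of the protein-coding AA467197.

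The number of calls depended on the scaling, while each scaling kept all 6 of these calls. Beside the 5 higher and 1 lower with TMM factors, RLE factors gave 7 and 8, total counts alone 17 and 1, upper quartile factors 6 and 39, and the library totals behind the authors' RPM values 121 and 2. The median log2 fold change of all rows shifted from that with TMM by 0.00, 0.29, -0.29 and 0.79 in that order, so fold changes are relative to the typical miRNA. At an unadjusted p under 0.05, 57 rows were higher and 62 lower. The groups did not overlap in 31.1% of rows, where chance gives 10%. Leaving out 1 library kept the calls of miR-21a-3p, miR-223-3p and miR-18a-5p in all 6 cases, those of miR-147-3p in 2, and those of miR-212-5p and the predicted miRNA in 1 each.

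**Figure D1:**
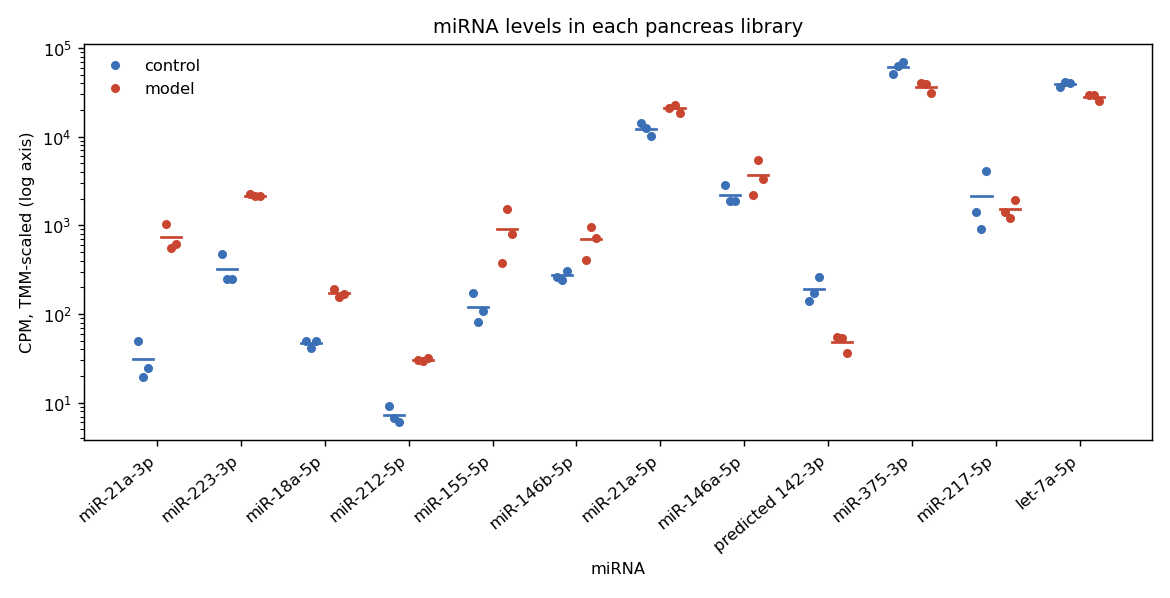
TMM-scaled CPM on a log axis for 12 miRNAs in each library, with a point per library (3 control, 3 model) and a bar at each group mean. For miR-223-3p the model libraries lie between 2121 and 2232 CPM and the controls between 246 and 471, while the groups overlap for miR-217-5p and miR-146a-5p.

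miRNAs that LPS and NF-kB signalling induce rose as a list, with members that differed among themselves. The model group received LPS with caerulein and no group received either alone, so their effects cannot be told apart. Of 12 tested members of that list, 3 were higher over all rows tested and 8 were higher when adjusted over the list alone, with a median log2 fold change of 1.36 (camera adjusted p = 2.0e-10; adjusted p = 0.146 with an estimated correlation). The members past the threshold over all rows were miR-21a-3p, miR-147-3p and miR-212-5p. The macrophage and lymphocyte activation miRNA miR-155-5p was at 121 ± 46.6 CPM in control and 907 ± 589 in model libraries (log2 fold change 2.91, SE 0.55), with an edgeR adjusted p = 0.0564. The adjusted p of miR-155-5p lay on both sides of the threshold under the alternatives, from 9.5e-07 with DESeq2 (log2 fold change 2.89) and 0.0486 with RLE factors to 0.162 without model replicate 59. Major-strand miR-21a-5p was at 12264 ± 1972 and 20890 ± 2051 CPM (log2 fold change 0.77, edgeR adjusted p = 0.0564). This uncalled miRNA was the list's most abundant member (mean 16577 CPM, against 2932 for miR-146a-5p), so the list's share of counts largely follows it. For the NF-kB feedback miRNA miR-146a-5p the log2 fold change was 0.73 (SE 0.35, edgeR adjusted p = 0.246), and for its relative miR-146b-5p, named after its values were seen, 1.36 (SE 0.34, edgeR adjusted p = 0.0774). The list took 1.39% ± 0.339 of counts in control and 3.04% ± 0.346 in model libraries (SD, n = 3 each; exact permutation p = 0.1; adjusted p = 0.225 over 18 lists).

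The miR-17~92 and paralogous clusters, which are linked to proliferation, also rose as a list, with members that differed among themselves. Over all rows 1 of 16 tested members was higher, and 9 were higher when adjusted over the list alone, with a median log2 fold change of 0.83 (camera adjusted p = 8.7e-07; adjusted p = 0.146 with an estimated correlation). Besides miR-18a-5p, miR-17-5p had a log2 fold change of 1.09 (SE 0.22, edgeR adjusted p = 0.0564; named after its values were seen), miR-20a-5p one of 0.91 (SE 0.23, edgeR adjusted p = 0.0802) and the more abundant miR-92a-3p one of 0.33 (SE 0.20, edgeR adjusted p = 0.368). From a paralogous cluster, miR-93-5p did not rise, with a log2 fold change of -0.0031 (SE 0.22, edgeR adjusted p = 0.989). The share of counts of the list was 0.549% ± 0.0489 in control and 0.910% ± 0.157 in model libraries (SD, n = 3 each; exact permutation p = 0.1).

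Leukocyte-enriched miRNAs rose as a list, with members that differed among themselves. Over all rows 1 of 9 was higher, and 3 were higher when adjusted over the list alone, with a median log2 fold change of 0.56 (camera adjusted p = 0.0024; adjusted p = 0.533 with an estimated correlation). Beside miR-223-3p, the pan-leukocyte miR-142a-3p had a log2 fold change of 1.45 (SE 0.44, edgeR adjusted p = 0.111) and lay above all controls in each model library. Lymphocyte-enriched miR-150-5p, the most abundant member, was at 4404 ± 769 and 3454 ± 2228 CPM (log2 fold change -0.35, SE 0.47, edgeR adjusted p = 0.735), and its sign turned with the authors' totals (0.48) and without model replicate 56 (0.066). The call of the leukocyte-enriched list was kept in 14 of 18 alternatives and lost, among others, without control replicate 45 (adjusted p = 0.0558) and without model replicate 57 (adjusted p = 0.157). The share of counts was 0.519% ± 0.159 in control and 0.839% ± 0.309 in model libraries (SD, n = 3 each; exact permutation p = 0.2). Erythroid miRNAs, a measure of red blood cells in the tissue, gave no call (camera adjusted p = 0.801). Of their 7 members 0 passed over all rows or adjusted over the list alone. For miR-451a the log2 fold change was -0.37 (SE 0.21, edgeR adjusted p = 0.327), and 0.35 with the authors' totals.

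Pancreatic acinar-enriched miRNAs fell as a list relative to the other rows. All 8 tested members had negative log2 fold changes with TMM, 0 passed over all rows and 2 were lower when adjusted over the list alone, with a median of -0.49 (camera adjusted p = 0.0378; adjusted p = 0.524 with an estimated correlation). Acinar-cell miR-216a-5p went from 27827 ± 6775 to 20990 ± 1784 CPM (log2 fold change -0.41, SE 0.18, edgeR adjusted p = 0.219), miR-216b-5p from 7644 ± 586 to 5484 ± 260 CPM (-0.48, SE 0.14, edgeR adjusted p = 0.0995) and miR-148a-3p from 30600 ± 12233 to 20945 ± 484 CPM (-0.55, SE 0.25, edgeR adjusted p = 0.238). Of these, miR-216a-5p and miR-148a-3p were among the rows of at least 10000 CPM, whose median was -0.37. Control replicate 45 stood apart in 3 of these miRNAs, with 4138 CPM of miR-217-5p against 909 to 1947 in the other libraries, 35582 of miR-216a-5p against 19256 to 24841, and 44712 of miR-148a-3p against 20423 to 24089. Without it the log2 fold change of miR-217-5p turned from -0.50 to 0.37, and those of miR-216a-5p and miR-148a-3p were -0.22 and -0.20. The share of counts of the list was 6.52% ± 1.61 in control and 5.76% ± 0.231 in model libraries (SD, n = 3 each; exact permutation p = 0.7), with 8.34% in control replicate 45, 5.97% and 5.26% in the other controls and 5.49% to 5.90% in model libraries. The call of the pancreatic acinar-enriched list was kept in 10 of 18 alternatives and lost, among others, without that library (adjusted p = 0.277), without model replicate 57 (adjusted p = 0.156), with total counts alone (adjusted p = 0.0604) and with the authors' totals (adjusted p = 0.286), under which these 4 miRNAs turned positive, from 0.30 for miR-148a-3p to 0.41 for miR-217-5p. Islet-enriched miRNAs gave no list call (camera adjusted p = 0.655; 0 of 7 past the threshold over all rows and 1 lower when adjusted over the list alone). Beta-cell miR-375-3p, the most abundant row of every library, was at 60741 ± 9427 CPM in control and 36724 ± 5099 in model libraries (log2 fold change -0.73, SE 0.15, edgeR adjusted p = 0.0611; 0.085 with the authors' totals). The islet-enriched share was 6.50% ± 0.585 and 5.36% ± 0.580 (SD, n = 3 each; exact permutation p = 0.1). This difference changed sign once miR-375-3p was taken out.

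The let-7 family, which marks differentiated cells, fell as a list. Of 17 members 0 passed over all rows and 9 were lower when adjusted over the list alone, 2 of which share a sequence and its counts and so are 1 measurement, with a median log2 fold change of -0.39 (camera adjusted p = 0.00585; adjusted p = 0.524 with an estimated correlation; let-7 family adjusted p = 0.0628 with the authors' totals). The abundant let-7a-5p, let-7c-5p and let-7f-5p had log2 fold changes of -0.50, -0.51 and -0.46 (SE 0.11, 0.12 and 0.10, edgeR adjusted p = 0.0731 for each), and with the authors' totals these were 0.30, 0.29 and 0.33. Other abundant rows had values of this size as well: the 32 rows of at least 10000 CPM had a median of -0.37, with 30 negative, and the 7 let-7 members among them ran from -0.51 for let-7c-5p to -0.18. Scarcer 3p arms spread more widely. The log2 fold change was -2.82 for let-7c-1-3p (mean 6.64 CPM), -1.31 for let-7e-3p and -1.32 for the shared sequence of let-7a-1-3p and let-7c-2-3p. It was 0.98 for let-7i-3p, and 4 of the 17 members had positive values. Near-identical sequences make the split of reads between let-7 members uncertain. Their combined share of counts was 21.2% ± 0.818 in control and 20.1% ± 0.490 in model libraries (SD, n = 3 each; exact permutation p = 0.2). The other most abundant rows, miR-26a-5p and miR-22-3p, had log2 fold changes of -0.60 (SE 0.12, edgeR adjusted p = 0.0564) and -0.47 (SE 0.13, edgeR adjusted p = 0.0923), and 0.21 and 0.32 with the authors' totals.

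The rodent-specific Sfmbt2 intron cluster rose as a list. Of 26 members, several of which share a sequence with another, 0 passed over all rows or adjusted over the list alone, and 23 had positive log2 fold changes, with a median of 0.31 (camera adjusted p = 0.0261; adjusted p = 0.223 with an estimated correlation). Its most abundant member, miR-467a-5p, was at 182 ± 55.1 and 307 ± 32.4 CPM (log2 fold change 0.75, SE 0.28, edgeR adjusted p = 0.157). The cluster took 0.0441% ± 0.00323 of counts in control and 0.0784% ± 0.00542 in model libraries (SD, n = 3 each; exact permutation p = 0.1). The call of the Sfmbt2 intron cluster was kept in 11 of 18 alternatives and lost, among others, without model replicate 57 (adjusted p = 0.0876), with total counts alone (adjusted p = 0.0548) and with the authors' totals (adjusted p = 0.244).

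**Figure D2:**
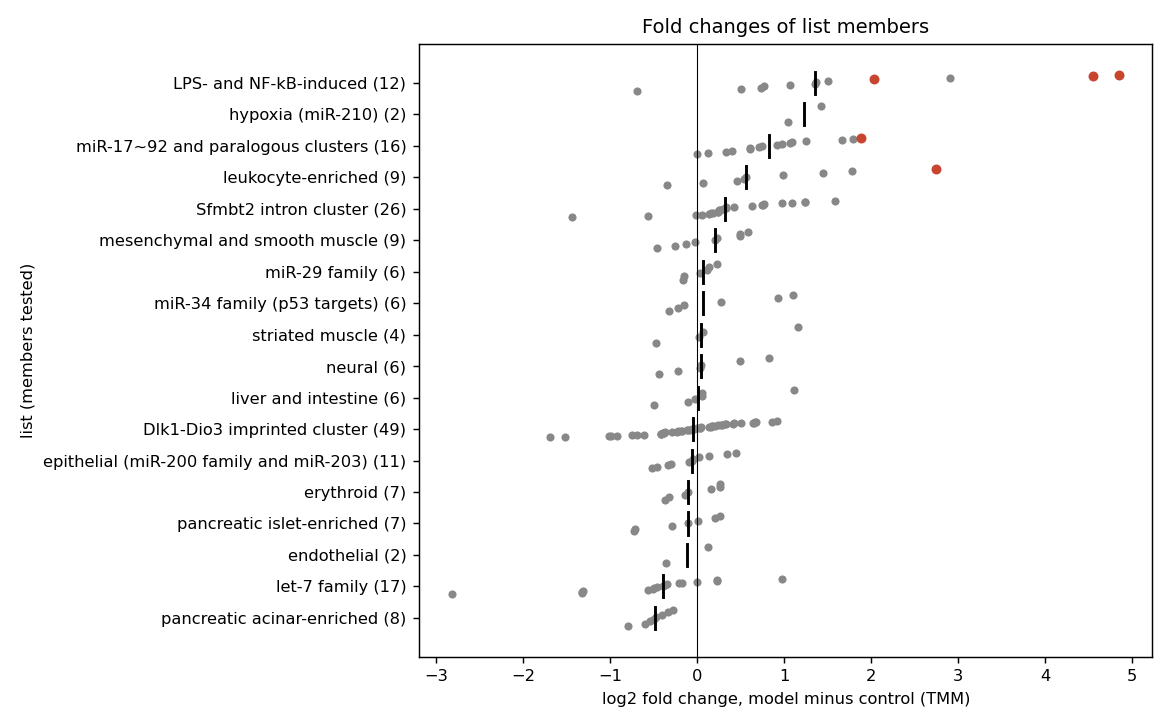
Log2 fold change, model minus control with TMM scaling, of each tested member of the 18 lists, with a black bar at each list's median and red points for members with an adjusted p under 0.05 over all rows. The medians run from -0.49 for the acinar-enriched list to 1.36 for the LPS- and NF-kB-induced list.

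The other lists gave no call with camera. The camera adjusted p was 0.691 for the epithelial, 0.691 for the mesenchymal and smooth muscle, 0.812 for the striated muscle, 0.801 for the liver and intestine, 0.801 for the neural, 0.878 for the miR-29 family, 0.691 for the miR-34 family and 0.691 for the Dlk1-Dio3 list. In these, 0 members passed over all rows, and when adjusted over the list alone 2 of 11 epithelial members were lower and 0 members of the rest passed. Epithelial miR-200c-3p had a log2 fold change of -0.34 (SE 0.12, edgeR adjusted p = 0.157; 0.47 with the authors' totals) and smooth muscle miR-143-3p one of -0.26 (SE 0.21, edgeR adjusted p = 0.537; 0.041 with total counts alone and 0.51 with the authors' totals). The endothelial and hypoxia lists had 2 tested members each and were not tested as lists. Endothelial miR-126a-3p had a log2 fold change of -0.36 (SE 0.13, edgeR adjusted p = 0.157; 0.43 with the authors' totals; 0 of 2 past the threshold when adjusted over the list alone), and hypoxia-induced miR-210-3p one of 1.42 (SE 0.48, edgeR adjusted p = 0.137; 1 of 2 higher when adjusted over the list alone). No list was called with an estimated correlation, and fry's directional form called the LPS- and NF-kB-induced and the miR-17~92 lists (adjusted p = 0.0173 for both). Fry's mixed form, which takes changes in both directions together, had an adjusted p under 0.05 for every list that camera called. It also had one for the epithelial (0.0111), Dlk1-Dio3 (0.0105), islet-enriched (0.0282) and miR-34 family (0.0441) lists.

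The ratio of both arms of a hairpin does not depend on scaling between libraries. Of the hairpins tested, miR-21a alone passed the threshold for a changed ratio. Its 5p arm outnumbered the 3p arm 415 times in control and 29.4 times in model libraries. The log2 ratio was 8.70 ± 0.58 against 4.88 ± 0.50 (SD, n = 3 each) and fell by 3.82 (SE 0.42, limma adjusted p = 0.00505). Each model library lay below each control. The call held without any 1 library, with the highest adjusted p at 0.0444. At an unadjusted p under 0.05, 19 hairpins differed.

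**Figure D3:**
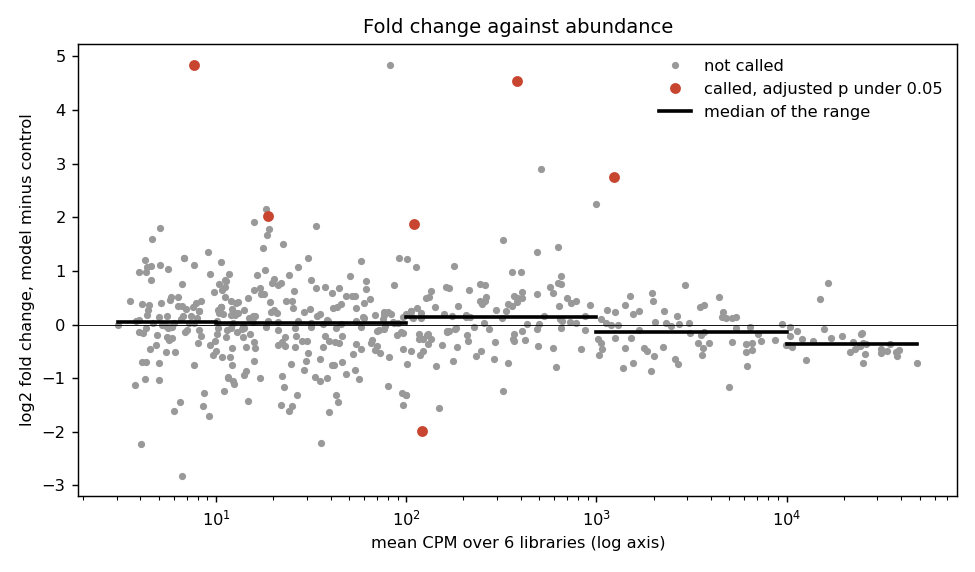
Log2 fold change, model minus control with TMM scaling, against mean CPM on a log axis for the rows tested, with red points for the 6 called and black bars at the median of each abundance range. The median was -0.37 over the 32 rows of at least 10000 CPM, of which 30 were negative, and 0.14 over the 113 rows from 100 to 1000 CPM.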

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

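Scaling by the authors' totals, keeping identical sequences once and the newer quasi-likelihood dispersion were chosen after seeing the data, and the other settings before the data were examined. The 5 higher and 1 lower miRNAs became 7 and 8 with RLE factors, 17 and 1 with total counts, 6 and 39 with upper quartile factors, 121 and 2 with the authors' totals, 23 and 35 with no filter, 8 and 7 with known miRNAs only, 4 and 2 with the newer dispersion, and 17 and 16 with DESeq2. DESeq2 called all 6 of the original calls. Limma-voom, a log2 fold change of at least 1 and keeping identical sequences once each gave 5 and 1, and the 10 CPM filter 4 and 1. Leaving out 1 library gave 3 to 5 higher (3 without control replicate 44, control replicate 45 or model replicate 57) and 0 to 5 lower (5 without control replicate 43, and 0 without any other single library). Lists called, 6 at first, were 4 with total counts, with the 10 CPM filter and with the more abundant arm only. They were 3 with the authors' totals, 0 with an estimated correlation and 2 with fry's directional form. With 1 library left out they were 3 to 6 (3 without model replicate 57). Fewer libraries leave fewer degrees of freedom, though lower calls rose to 5 without control replicate 43. The cause was not tested for any of these moves. The count of arm ratios called as changed stayed at 1 under every setting run for it. No paired analysis was possible because the groups share no replicate number.

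With the authors' totals, which raise the median of all rows by 0.79, the log2 fold change turned positive for miR-150-5p (0.48), miR-451a (0.35), let-7a-5p (0.30), let-7c-5p (0.29), let-7f-5p (0.33), miR-216a-5p (0.41), miR-216b-5p (0.32), miR-217-5p (0.41), miR-148a-3p (0.30), miR-375-3p (0.085), miR-22-3p (0.32), miR-26a-5p (0.21), miR-126a-3p (0.43), miR-200c-3p (0.47) and miR-143-3p (0.51), and with total counts for miR-143-3p (0.041). None of these was called with TMM. With 1 library left out, miR-217-5p ran from -0.87 to 0.37 and miR-150-5p from -0.93 to 0.066. Lists never called by camera or by fry's directional form turned direction, with camera adjusted p-values far from the threshold. These were the miR-29 family with upper quartile factors (0.921) and no filter (0.886), and striated muscle with the 10 CPM filter (0.888). With the authors' totals they were epithelial (miR-200 family and miR-203) and liver and intestine (0.853 each). Over left-out libraries they were liver and intestine (0.531 to 0.974), striated muscle (0.531 to 0.975), erythroid (0.283 to 0.974), neural (0.505 to 0.991) and Dlk1-Dio3 imprinted cluster (0.238 to 0.991). The cause was not tested. The difference in share of the pancreatic islet-enriched list moved by more than 1 SD, from -1.14 to 0.237 percentage points, once its own most abundant member was taken out. Depth limits rows near the floor, such as miR-147-3p, and 816 of the 1414 rows averaged fewer than 5 counts.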

Other observations

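All tests in this part were chosen only after the result was seen, except the omission of single libraries from the arm ratios, which was fixed before. Neighbouring hairpins within 10 kb were grouped into 35 clusters and tested with camera, and 3 were called, none of them with an estimated correlation (adjusted p = 0.299 for each). The Mir17 to Mir92-1 cluster on chromosome 14, from 115043671 to 115044506, had positive log2 fold changes in 10 of 10 arms (median 1.02, adjusted p = 1.0e-06). Mir212 and Mir132, which lie together on chromosome 11 from 75173388 to 75173747, were positive in 4 of 4 arms (median 1.43, adjusted p = 0.00172). Part of the Sfmbt2 cluster on chromosome 2, from 10467229 to 10489202, was positive in 14 of 14 arms (median 0.75, adjusted p = 0.0034), some of which share a sequence, while the other part, from 10505721 to 10514971, was positive in 9 of 11 (median 0.24, adjusted p = 0.837). The Mir25, Mir93 and Mir106b cluster on chromosome 5, a paralogue of the first, was positive in 3 of 4 arms (median 0.36, adjusted p = 0.608), and the difference between these paralogues was not tested.

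Of the counts in predicted rows, 72.3% lay in 6 rows whose sequence ends in CCA, the tail of mature tRNAs, and 9.72% in 21 rows whose sequence matched an annotated snoRNA. In model replicate 59, miR-103-3p reached 4135 CPM against 315 to 415 in the other 5 libraries, and miR-202-5p reached 447 CPM against 1.23 to 29.3. The share of miRNA counts in the totals behind the authors' RPM values was 8.45% ± 1.16 in control and 11.9% ± 1.70 in model libraries (SD, n = 3 each; exact permutation p = 0.1, the smallest possible).

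Whether chance regrouping alone gives as many calls cannot be settled with 10 splits of the 6 libraries. Each other split also puts libraries of both groups on each side, so a real group difference could widen its spread and lower its calls. The real split gave 5 higher miRNAs, more than any other (highest 1), so 1 of 10 splits reached it. It gave 1 lower, which 2 of 10 splits reached. It gave 6 lists, which 1 of 10 reached, although control replicates 43 and 45 with model replicate 56 against the rest gave 5. It gave 1 arm ratio, which 1 of 10 reached, and the others gave 0.

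The most abundant miRNAs sat lower in the model group with TMM, at a median log2 fold change of -0.37 over 32 rows. Scaling sets that direction: the median of these rows reached 0.42 with the authors' totals, while their distance to the median of all rows stayed between -0.36 and -0.38 under the 5 scalings. A ceiling on the counts of abundant rows cannot be told apart from a real shift, since within groups their raw counts followed those of 150 rows of 100 to 3000 CPM with a slope of 0.806 (95% interval 0.370 to 1.24), too wide to exclude either. A broader mix of miRNAs in the model tissue stays open and untested.

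The larger increase of miR-21a-3p than of miR-21a-5p was set against technical sources. Its sequence was held by 1 annotated hairpin, so reads shared with another hairpin do not account for it, though transcripts of Vmp1 hold it too and stay open as a source of fragments, and no single library carried it, since the highest adjusted p with 1 left out was 0.0444. A first test of a ceiling on miR-21a-5p, replaced once its result was seen, left that source open: the minor arm of 17 other abundant hairpins changed by a median of 0.50 more than the major arm (-0.59 to 1.28). In the test put in its place, a ceiling as the whole cause would need a slope of 0.169. That lies below the interval of 0.370 to 1.24 measured for the median of abundant rows. It argues only against a ceiling of that strength common to abundant rows. The slope of miR-21a-5p itself was not measured, so a ceiling on that arm stays open. A hypothesis is that newly made hairpins may raise the 3p arm at 24 hours, before the 3p strand is lost. All libraries were taken at 24 hours, so it was not tested here.

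The rise of miR-223-3p, a myeloid miRNA, was set against other blood cells. More blood of unchanged composition would raise erythroid miR-451a as well. The log2 fold change of miR-451a was -0.37 with an upper bound of 0.05 at 2 SE, below the lower bound of 2.12 for miR-223-3p. Because miR-451a follows red cells, the same amount of blood with more myeloid cells in it stays open. An equal rise of all leukocytes would leave the ratio of miR-223-3p to lymphocyte-enriched miR-150-5p in place, and that log2 ratio rose by 3.38 (SE 0.64). Of the 9 tested leukocyte-enriched members 8 had positive log2 fold changes, and miR-150-5p was the exception. Pan-leukocyte miR-142a-3p had one of 1.45 (SE 0.44, edgeR adjusted p = 0.111), so the size of such a ratio depends on the member chosen. A candidate explanation is an influx of neutrophils or other myeloid cells, for which no cell count was analysed here. A change of miR-223-3p within resident cells stays open.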
